A study of Yarrowia lipolytica with 3 samples.

How the data were processed

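Total RNA was measured by RNA-seq in 3 cultures of Yarrowia lipolytica, 1 per strain (wild type, mhy1 deletion, MHY1 overexpression). Per the labels' protocols, each 50 ml culture was grown at 30 °C to an OD600 of 0.8, and 1 µg of RNA went into an Illumina TruSeq RNA library; whether the libraries keep strand is not given in the sources used here. Per the file headers, the deposited values are RPKM, a read number scaled to gene length and library size, for 6448 gene identifiers per library. Per the submitters' processing notes, TopHat2 2.1.1 and Cufflinks 2.2.1 were named, without a role, together with a mouse genome build, which cannot be the source of Yarrowia identifiers. The yeast build, the annotation and the counting settings are not given in the sources used here. The plan written beforehand had assumed FPKM; RPKM was used in the same way.

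Low RPKM values lay on whole-read steps. From these steps the relative depth of the libraries, their read totals and each gene's coding length were recovered, and 99.98% of values above 0 came out within 0.01 of a whole read. The recovery took multiples of 3 first, so their share is no evidence that the lengths are coding lengths. They were read as coding lengths without untranslated regions, on which the name check below bears. For some genes the recovered length is a fraction of the true one and the reads are too low by the same factor, which widens the counting intervals. Tested on simulated data for 6387 genes with lengths in multiples of 3, 99.97% of recovered lengths equalled or divided the true one and 92.3% equalled it. For the deletion comparison, simulated folds of 1.5, 2, 4 and 0.25 came back as 1.49, 1.96, 3.95 and 0.259 (38, 43, 39 and 36 genes).

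Ratios were log2((x + 1)/(y + 1)) on RPKM, so folds of weak genes are understated on that scale; folds printed as such are plain RPKM ratios. The 6035 genes at 1 RPKM or more in at least 1 library were compared, and a gene was called at 2-fold or more on the log2 scale. With 1 library per group no test was run. Each RPKM ratio has an exact conditional binomial interval (95%) from the recovered reads. A gene listed at 0 was set against a floor of 3 reads.

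Genes to be named were fixed before the data were examined: MHY1; the 10 highest and 10 lowest ratios of each strain against wild type among genes at 10 RPKM or more in 1 of the libraries; the 10 genes most clearly ordered with and against MHY1; and list members at least 2-fold different or needed to describe a list. The neighbours of MHY1 were added after its values were seen. None of the 6448 identifiers matched the reference table of assembly ASM176148v1 (0 matched), and the files do not pair identifiers with names, so genes outside the lists are printed by identifier, at most 2 per direction. The names of list members were assigned from general knowledge of Yarrowia nomenclature, with no annotation table, and were checked by length. The check used whichever whole multiple, up to 5, of the recovered length came nearest the expected one, for names and random identifiers alike. HOY1 (recovered at 306 bp), POX5 (1050 bp), POX6 (1035 bp), GLK1, TPI1, PYK1, SCT1 and MDH2 needed a multiple above 1. Of 67 names, 62 were kept. For 28 of these the expected length was that of the Yarrowia protein, as recalled, and 25 agreed exactly, where 0.303% of identifiers drawn at random would. For 34 it was that of the Saccharomyces cerevisiae protein, within 15%; that check is weak, since 43.4% of random identifiers would pass it, although 28 of the 36 names tested lay within 5%, where 15.0% of random identifiers would. All the glycolysis names except HXK1, all the citrate and glyoxylate names except ICL1, and FAS2, MAE1, ELO1, ELO2, GPD1, SCT1, SLC1, TGL3, TGL4 and GUT2 rest on it. The 5% tolerance for Yarrowia lengths was set after the lengths were seen. LEU2, PAH1 and GUT1 missed their length, and URA3 and XPR2 are not used here.

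Of 16 lists fixed in advance, 4 were analysed (glycolysis and gluconeogenesis; citrate and glyoxylate cycles; fatty acid and lipid synthesis; lipid breakdown and β-oxidation). For each, the median log2 ratio is given with a 95% order-statistic interval, and its percentile among 10000 random lists matched in 20 bins of mean expression. The other 12 lists needed gene descriptions or had under 5 checked members and were not analysed as lists. A promoter motif search needs a genome and was not analysed here.

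To see what the shared wild-type library alone gives, 100 draws were made with equal unrelated noise in the 3 libraries, and 100 with counting noise alone in the reads. The equal noise was Gaussian, of the same size for every gene. In 100 further draws genes were shuffled, which holds no shared library. The planned estimate of wild-type noise from the pairwise ratios was below 0 and was set to 0, which is the shuffle. Alternatives tried were pseudocounts of 0.1 and 5, no filter and a filter at 10 RPKM, median of ratios and upper-quartile scaling, and thresholds of 1.5-fold and 4-fold; thinning to the wild-type total, centring on the median ratio and other ways to form the lowest expression decile were chosen after seeing the data. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.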

Results

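The data set held 3 RNA-seq libraries of the dimorphic, oil-accumulating yeast Yarrowia lipolytica, 1 each from the wild-type strain PO1a, an mhy1Δ strain lacking MHY1 and a strain overexpressing MHY1. MHY1 encodes a C2H2 zinc-finger transcription factor known for its role in the switch from yeast to hyphal growth. All 3 cultures were grown at 30 °C in defined medium with uracil and taken at an OD600 of 0.8. Expression was given as RPKM for 6448 genes. The values implied totals of 47622181 reads for wild type, 59527000 for the deletion strain and 75306802 for the overexpression strain. The recovered reads of the listed genes made up 95.9%, 95.8% and 96.0% of these totals. Those shares are lower limits, since the reads recovered for some genes are too low. With 1 library per group, no difference below has a replicate check, and genes are named by the size of the difference between libraries. The 95% intervals given with ratios of single genes cover counting error only. Those given with list and decile medians cover the spread between genes, which are not independent replicates. The files pair no identifiers with names, so gene names rest on identifier lists fixed in advance and checked by coding length.

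MHY1 (YALI0B21582g) followed the strain labels. It was at 467 RPKM in wild type (19064 reads), was listed at 0 in the deletion strain and was at 1159 RPKM in the overexpression strain (74881 reads). A read number of 0 allows up to 3 reads, or 0.0587 RPKM, in the deletion library, so MHY1 was at least 7943-fold higher in wild type. In the overexpression library it was 2.48-fold higher than in wild type (interval 2.44 to 2.52). Of the genes on either side of it in identifier order, YALI0B21560g was at 123, 120 and 113 RPKM in wild type, deletion and overexpression, and YALI0B21604g at 80.6, 98.0 and 114 RPKM, 1.41-fold higher in overexpression than in wild type (1.32 to 1.51).

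The comparison of the deletion strain with wild type addressed which transcripts depend on MHY1. All 13 genes listed for the citrate and glyoxylate cycles had log2 ratios above 0, with a median of 0.43 (interval 0.23 to 0.63, percentile 100 among 10000 random lists matched on expression). The median of these random lists was 0.07, and 12 of the 13 genes were within 2-fold. MLS1, a malate synthase, was at 17.7 RPKM in wild type and 54.5 in the deletion, 3.08-fold higher (2.90 to 3.27), and ICL1, isocitrate lyase of the glyoxylate cycle, was at 732 and 1464 RPKM. The ICL1 log2 ratio of 1.00 lay just under the 2-fold line and passed it under both other scalings. The malate dehydrogenase genes MDH1 and MDH2 were 1.52-fold and 1.55-fold higher.

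Of the 13 glycolysis and gluconeogenesis genes, 11 had log2 ratios above 0 in the deletion strain, with a median of 0.21 (0.02 to 0.34, percentile 97.6). PCK1, phosphoenolpyruvate carboxykinase, was the only member at least 2-fold different, at 598 RPKM in wild type and 1385 in the deletion, 2.32-fold higher (2.29 to 2.34). The 17 fatty acid and lipid synthesis genes had a median of 0.23 (−0.02 to 0.40, percentile 99.8), and 1 of them, the malic enzyme gene MAE1, was at least 2-fold higher, at 15.4 and 33.5 RPKM. Within that list the elongase gene ELO2 (580 and 328 RPKM) and the diacylglycerol acyltransferase gene DGA1 (75.8 and 45.6 RPKM) went the other way. The 11 lipid breakdown and β-oxidation genes went both ways, with a median of −0.02 (−0.94 to 0.58, percentile 42.2), whose sign turned under upper-quartile scaling. Among the acyl-CoA oxidase genes, POX5 was 2.36-fold higher (2.22 to 2.50) and POX6 was 2.46-fold lower (2.27 to 2.68).

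Across the 6035 genes compared, 100 were at least 2-fold higher and 352 at least 2-fold lower in the deletion library, and at 4-fold these counts were 17 and 79. With a pseudocount of 5 RPKM, 211 were at least 2-fold lower. The largest differences among genes without a name were downward. YALI0C23452g was at 837 RPKM in wild type and 1.23 in the deletion, 683-fold lower (590 to 794), and YALI0A00176g at 465 and 2.15 RPKM, 216-fold lower (194 to 242). Upward, YALI0F01210g was at 38.1 and 418 RPKM and YALI0E07744g at 18.3 and 198 RPKM. The counting interval of the RPKM ratio lay beyond 2-fold for 415 of the 452 genes called.

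The comparison of the overexpression strain with wild type addressed which transcripts respond to extra MHY1. Of the 11 genes of lipid breakdown and β-oxidation, 4 were at least 2-fold higher, 1 was at least 2-fold lower and 6 were within 2-fold, with a median log2 ratio of 0.72 (−0.33 to 1.56, percentile 100). TGL3, a triacylglycerol lipase gene, was at 28.4 RPKM in wild type and 106 in the overexpression strain, 3.75-fold higher (3.60 to 3.91). POX2 was 2.93-fold higher (2.86 to 3.01), POT1, the peroxisomal thiolase gene, 2.95-fold higher (2.89 to 3.01) and POX3 2.35-fold higher (2.30 to 2.39). POX5 stood apart from the other oxidase genes, at 30.2 and 9.75 RPKM, 3.09-fold lower (2.83 to 3.38).

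All 13 glycolysis and gluconeogenesis genes had log2 ratios below 0 in the overexpression strain and none reached 2-fold. Their median was −0.28 (−0.44 to −0.20, percentile 1.77), where the median of the matched random lists was −0.09. PCK1 was at 335 RPKM, 1.78-fold lower than in wild type (1.76 to 1.81), and the aldolase gene FBA1 was 1.43-fold lower. The citrate and glyoxylate cycle genes had a median of −0.20 (−0.36 to 0.16, percentile 9.64), with 10 of 13 log2 ratios below 0 and 3 above. ICL1 was among the latter, at 822 RPKM and 1.12-fold higher than in wild type (1.11 to 1.13). MLS1 was the member at least 2-fold lower, at 7.41 RPKM, 2.39-fold lower than in wild type. The fatty acid and lipid synthesis genes had a median of −0.10 (−0.39 to 0.18, percentile 12.3), with the acetyl-CoA carboxylase gene ACC1 1.59-fold lower, the fatty acid synthase genes FAS1 and FAS2 1.31-fold and 1.48-fold lower, and the acyltransferase gene DGA2 1.92-fold higher.

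In all, 361 genes were at least 2-fold higher and 149 at least 2-fold lower in the overexpression library, so that 70.8% of these genes were higher; after centring the ratios on their median over all genes the share was 57.2%. At 4-fold the counts were 51 and 39. With a pseudocount of 5 RPKM, 188 genes were at least 2-fold higher, and among genes at 10 RPKM or more 238 were. YALI0A00374g was at 2.01 RPKM in wild type and 259 in the overexpression strain, 129-fold higher (104 to 162), and YALI0A17666g at 2.32 and 99.3 RPKM, 42.8-fold higher. YALI0C03443g, at 2191 and 28.3 RPKM, was 77.5-fold lower (70.8 to 85.0), and YALI0C03465g, the next identifier, at 826 and 15.9 RPKM, was 52.0-fold lower. In the deletion library these last genes were at 2543 and 895 RPKM. The median log2 ratio was higher for weakly expressed genes, at 0.53 (0.48 to 0.57) in the lowest decile of mean expression and −0.09 (−0.10 to −0.07) in the highest. Of the lowest-decile genes 26.3% passed the 1 RPKM filter by their overexpression value alone, which inflates the first value; without them the median was 0.39 (0.30 to 0.46), and in the lowest decile of all genes with a read it was 0.25 (0.21 to 0.29).

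**Figure D1:**
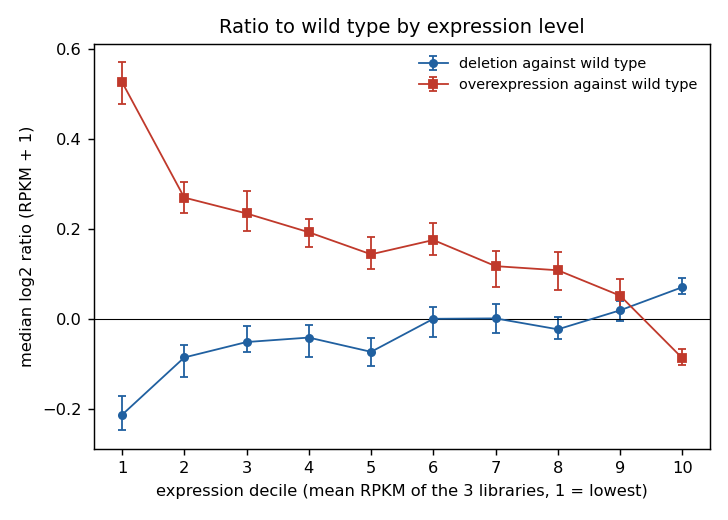
Median log2 ratio to wild type, with 95% order-statistic intervals as bars, by decile of mean RPKM over the 3 libraries, for the deletion strain (blue circles) and the overexpression strain (red squares). The overexpression medians go from 0.53 in the lowest decile to −0.09 in the highest, and the deletion medians from −0.21 to 0.07; the lowest decile includes genes that passed the filter in the overexpression library alone.

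Both ratios together showed which genes were ordered with MHY1 across the libraries, lowest in the deletion and highest in the overexpression strain. Besides MHY1 itself, YALI0A00176g, YALI0A00374g and YALI0A17666g were of this kind, and 107 genes in all were at least 2-fold lower in the deletion and at least 2-fold higher in the overexpression library. YALI0A00374g and YALI0A17666g passed the deletion side only narrowly, with log2 ratios of −1.05 and −1.02 at 0.45 and 0.64 RPKM in the deletion library. YALI0F07535g, among the 10 genes most clearly ordered with MHY1, was at 380, 3.71 and 2727 RPKM in wild type, deletion and overexpression. MLS1 and POX5 were in the opposite order, higher in the deletion and lower in the overexpression library by at least 2-fold, among 37 genes. Independent lists of these sizes would share 21.1 and 2.47 genes. The first count depended on the pseudocount: it was 200 at 0.1 RPKM, where independent lists would share 41.7, and 47 at 5 RPKM, where they would share 6.57. Of the 79 genes at least 4-fold lower in the deletion, 40 were at least 2-fold higher in the overexpression library, 38 were within 2-fold and 1 was lower. Of the 39 genes at least 4-fold lower in overexpression, 10 were at least 2-fold higher in the deletion library, 28 were within 2-fold and 1 was lower. Genes higher in both strains numbered 9, where independent lists would share 5.98, and genes lower in both numbered 7, where they would share 8.69.

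Simulated values were set beside these counts. Shuffling genes gave 21.2 genes on average in the order of MHY1 and 31 at most in 100 draws, and 2.53 and 7 in the opposite order. The shuffle holds no shared library and restates the independent lists, so it says nothing of the wild-type library that the ratios share. With equal unrelated noise in the 3 libraries the averages were 3.98 and 4.19, and the highest 9 and 11. That noise was Gaussian and of the same size for every gene, a shape the measured ratios were not shown to have. These counts are therefore not comparable with the observed ones. Across genes, which are not independent replicates, the ratios had a covariance of −0.13 (Pearson r −0.33, Spearman −0.26). The simulated covariance was 0.000544 for shuffled genes and 0.00246 for counting noise alone, and the observed value minus the latter was −0.13. For equal noise it was 0.30, a value set in advance by the size of the noise put in.

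**Figure D2:**
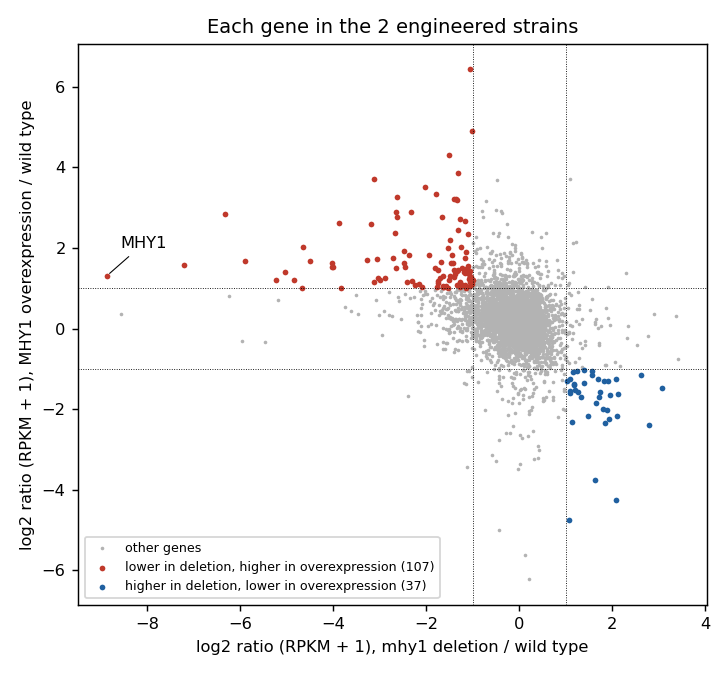
Log2 ratio (RPKM + 1) of each of the 6035 genes in the deletion strain (horizontal axis) and in the overexpression strain (vertical axis), each relative to wild type, with dotted lines at 2-fold. Red points mark the 107 genes lower in the deletion and higher in the overexpression library, with MHY1 at the far left, and blue points mark the 37 genes in the opposite order.

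The comparison of the overexpression strain with the deletion strain used no wild-type library and spanned the widest range of MHY1. Here 7 of the 11 lipid breakdown and β-oxidation genes were at least 2-fold higher and 1, POX5, at least 2-fold lower, with a median log2 ratio of 1.24 (−0.67 to 1.96, percentile 99.98). After centring 6 were at least 2-fold higher, TGL4 falling under 2-fold. MFE1 went from above 0 to below 0 under both other scalings and after centring. TGL3 was 5.81-fold higher (5.56 to 6.08) and POX6 4.09-fold higher, while POX5 was 7.29-fold lower (6.76 to 7.88). All 13 citrate and glyoxylate cycle genes had log2 ratios below 0, with a median of −0.72 (−0.87 to −0.33, percentile 0.020). The median of the matched random lists was −0.16. MLS1 was 7.36-fold lower and MLS2 1.05-fold lower. The glycolysis and gluconeogenesis genes had a median of −0.51 (−0.72 to −0.31, percentile 0.635), with PCK1 4.13-fold lower, and the fatty acid and lipid synthesis genes had a median of −0.45 (−0.79 to 0.12, percentile 0.075). The members of this last list went both ways: 7 of 17 log2 ratios were above 0 (5 under median of ratios scaling, 4 under upper-quartile scaling and 3 after centring), ELO2 and DGA1 were 2.32-fold and 2.31-fold higher, DGA1 falling under 2-fold after centring, and MAE1 and ELO1 were at least 2-fold lower.

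Over all genes, 906 were at least 2-fold higher and 286 at least 2-fold lower in the overexpression than in the deletion library. The share of higher genes among these was 76.0%, and 63.9% after centring. With a pseudocount of 5 RPKM, 591 genes were at least 2-fold higher. The median log2 ratio of all genes was 0.20 as deposited, 0.10 under median of ratios scaling and 0.06 under upper-quartile scaling.

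**Figure D3:**
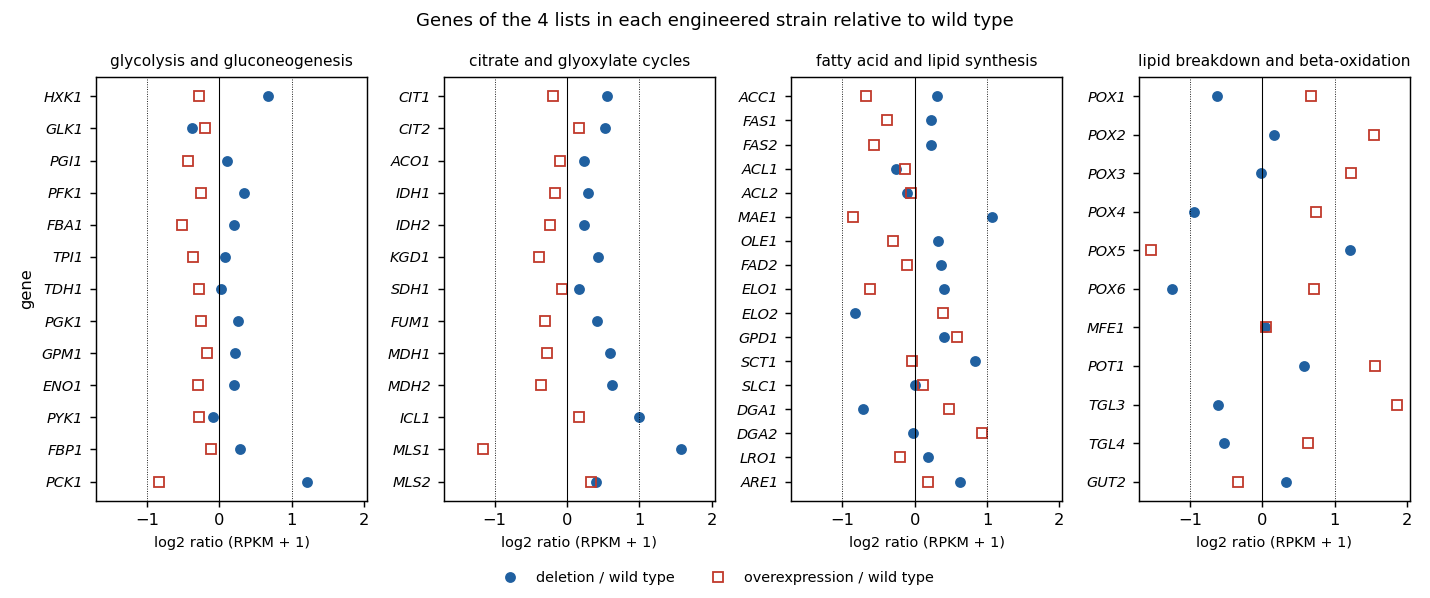
Log2 ratio (RPKM + 1) of each gene of the 4 lists in the deletion strain (blue circles) and the overexpression strain (red open squares) relative to wild type, 1 library per strain, with dotted lines at 2-fold. All 13 glycolysis and gluconeogenesis genes lie below 0 in the overexpression strain, and all 13 citrate and glyoxylate cycle genes above 0 in the deletion strain.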

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

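Thinning, centring and the other ways to form the lowest decile were chosen after seeing the data. At 2-fold, 42 of 48 counts under the other pseudocounts, filters and scalings stayed within 1.5 times of the reported ones. The counts without a filter could not move, since a gene under 1 RPKM in every library cannot reach 2-fold with a pseudocount of 1. With a pseudocount of 0.1, 200 genes were ordered with MHY1. With a pseudocount of 5, 211 genes were lower in the deletion, 188 higher in the overexpression strain, 47 ordered with MHY1 and 591 higher in overexpression than in deletion. With genes at 10 RPKM or more, 238 were higher in the overexpression strain. At 1.5-fold, 281 genes were higher and 785 lower in the deletion, 1013 higher and 339 lower in the overexpression strain, 324 ordered with MHY1 and 92 against it, and 1671 higher and 531 lower in overexpression than in deletion. At 4-fold these counts were 17 and 79, 51 and 39, 11 and 3, and 269 and 93. These 2 changes act by construction. So does the direction of the other moves, since the filter only removes genes, a larger pseudocount shrinks every ratio and a smaller one widens it. Thinning moves RPKM values very little and is left out of the next counts. Of 84 list medians over the alternatives, 81 kept their sign; the other 3 were the deletion median of lipid breakdown, near 0. Centring gave −0.44 for glycolysis in the overexpression strain and −0.92 for the citrate list between the engineered strains, where upper-quartile scaling gave −0.87. Of 692 values of named genes called at 2-fold, 680 stayed at least 2-fold in the same direction and none changed sign. A filter leaves every ratio as it is. Under the filters these values could not move, and list medians could move only by loss of a member. Few reads limit weak genes such as LIP7, with 46 in wild type. The lowest-decile median of 0.53 was 0.42, 0.25 and 0.39 with the decile formed among genes with a mean of 1 RPKM, among all genes with a read and without genes that passed by overexpression alone. No paired analysis was possible because each group had 1 library, which also rules out leaving out a replicate. The motif alternatives were not run.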

Other observations

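Genes from the lists too small to analyse showed further differences, with 1 library per strain. AOX1, the alternative oxidase gene of the respiratory chain, was at 197 RPKM in wild type, 505 in the deletion (2.56-fold higher, 2.50 to 2.62) and 101 in the overexpression strain (1.96-fold lower, 1.90 to 2.02). The secreted lipase genes differed in opposite directions: LIP8 was at 2684, 1365 and 4543 RPKM in wild type, deletion and overexpression, whereas LIP2 was at 873, 1237 and 537 RPKM. LIP7 and the acid protease gene AXP1 were near the low end, at 2.87 RPKM or less in every library. HOY1, a homeobox gene known for hyphal growth, was at 15.2, 16.0 and 31.7 RPKM, 2.08-fold higher with extra MHY1 (1.79 to 2.43); its log2 ratio of 1.01 passed the 2-fold line only narrowly and was 0.92 and 0.91, under it, with median of ratios and upper-quartile scaling. RIM101, the pH-response regulator, was at 219, 234 and 241 RPKM.

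All patterns below were noticed in these libraries before they were tested. The tests of scaling, of genes with almost no reads, of other ways to form the lowest decile and of the shared wild-type library were chosen only after the results they bear on were seen.

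Weakly expressed genes were higher in the overexpression library, with a median log2 ratio of 0.53 over the 604 genes of the lowest decile; selection inflates this, since 26.3% of them passed the filter by their overexpression value alone, and without them it was 0.39 (445 genes). Median of ratios scaling left the 604 genes at 0.47. Its factors, 0.986 for wild type and 1.05 for overexpression, were too close to move these ratios far. The value thus argues only against scaling of that size as the whole of the 0.53, a median that carries this selection. Thinning to equal depth (0.53) moves RPKM values very little anywhere and tests nothing. For a background that adds the same RPKM to every gene, the share of lowest-decile genes under 0.496 RPKM in the overexpression library (0.5 times their median gain of 0.993) was 2.32%, the outcome set in advance for a background as the cause; the test was judged void, because of the same selection, only after this was seen. A replacement test asked how many of 368 genes under 0.5 RPKM in wild type and deletion stayed under 0.5 times the gain with extra MHY1: 64.7% did at the gain of the 604 genes (63.9% at that of the 445 genes, 68.2% at that of the decile with a mean of 1 RPKM), and their own median gain was 0.169 RPKM, which argues against a uniform background as the whole of the 0.993 RPKM. For the lowest decile of all genes with a read, where the share was 23.9%, the test decides neither way. A background or scaling giving part of the gain, depth, culture differences and an effect of MHY1 itself stay open.

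Genes at least 2-fold different sat next to each other in identifier order more often than shuffled ones. In overexpression against wild type, 48 adjacent pairs were called in the same direction, against a mean of 23.8 and a highest value of 43 in 10000 shuffles; in deletion against wild type there were 37, against a mean of 20.9, a 95th percentile of 28 and a highest value of 40. Near-identical tandem copies sharing reads would have like lengths, but 8.33% of the overexpression pairs and 5.41% of the deletion pairs had coding lengths within 5%, beside 4.30% of all adjacent pairs. These are recovered lengths, which for some genes are a fraction of the true one, so some pairs of like length could be missed. A hypothesis is that some neighbouring genes differ together, as YALI0C03443g and YALI0C03465g did, a pair seen before the test. Reads running on from a strong gene into its neighbour, and overlapping genes counted without strand, could give the same excess of 48 pairs and stay open.

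More genes were ordered with MHY1 (107) than independent lists would share (21.1). The covariance of the ratios, −0.13, restates this excess and is no separate test. The control could not be split with 1 wild-type library. A difference in growth or handling that placed the cultures in the same order as MHY1 could give this as well as MHY1 itself, and no value here separates these.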
